A study of Homo with 2 samples.

How the data were processed

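Single-cell RNA sequencing was done on 2 libraries of 1 group: human blastoids, embryo-like aggregates grown from KhES1, an established human embryonic stem cell line. Per the labels, the cells were aggregated for 24 h in microwells and then kept for 4 days in hydrogel in medium with 10% fetal bovine serum and 10 µM of the ROCK inhibitor Y27632. Per the labels' protocols the libraries were made with droplet 3' chemistry, which counts unique molecular identifiers (UMIs). Per the submitters' processing notes, Cell Ranger 9.0.0 and the genome build GRCh38 were used. The authors deposited one table of raw UMI counts per library, by gene and cell barcode. Every barcode in these tables has at least 200 detected genes and every gene is detected in at least 2 barcodes; which step set those limits is not given in the sources used here.

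Barcodes with at least 1000 detected genes and at most 20% mitochondrial UMIs were kept. Of 1988 barcodes in library 1, 980 had too few genes and 71 too many mitochondrial UMIs; of 2601 in library 2, these numbers were 1013 and 69. Doublets were called per library with scrublet, in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. It marked 4 barcodes in library 1 and 2 in library 2, which were removed, leaving 933 and 1517 cells. The caller finds doublets of unlike cells only, so doublets of like cells stay in.

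Each UMI was assigned at random, with equal chance, to part A or part B. Part A was normalised to 10000 per cell, log-transformed and reduced to 2000 variable genes, without the genes of the fixed readout lists, mitochondrial genes and ribosomal protein genes. Cells were clustered from 30 principal components and 15 neighbours with the Leiden method at resolution 0.5 (igraph 0.11.9), with no batch correction. Clusters were named from 10 marker lists, and clusters of the same name form a class. A cluster stayed unnamed where its depth was under 1/3 of that of the sample with no marker of the name among its 10 leading genes, or where fewer than 3 markers were detected. Each list was scored by its mean log2 level in the cluster plus the excess of that level over the mean of the clusters not under the depth limit. The score was written after the data had been seen; the markers were fixed before.

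Part B UMIs were summed per library and class, for all classes and clusters with at least 20 cells in both libraries. Genes in both tables, 25556 of 28363, entered the tests. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, library as a block, Benjamini-Hochberg adjustment, threshold 0.05). The SE of a log2 fold change was taken as its size divided by the square root of the test's F statistic. It is not a counting error, so folds that rest on few UMIs are less certain than it shows. The libraries are the replicates, never the cells. With the library as a block, p-values measure only how far the differences between classes vary between these libraries, pooled over all classes and clusters in the fit. The labels do not say that the libraries came from separate cultures, so that spread may be technical. The 27 readout lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it (fry tests whether the genes of a list move one way on balance and does not compare them with other genes), adjusted over all lists and comparisons. A list count "adjusted over the list alone" adjusts the same p-values over its own members.

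The edgeR step was tested on simulated data for the trophectoderm/amnion-like against the epiblast-like class, with counts drawn for 12775 genes, of which 11392 were tested. It recovered 70 of 86 genes changed 2-fold (81.4%) and 90 of 93 changed 4-fold (96.8%), with 7 false calls and 0 calls of the wrong sign. The simulation gave all classes the same profile apart from these few genes, with rises and falls in equal number. It held no library effect and no difference in the mix of cells. It therefore does not show the errors of scaling possible in the data, where 6080 of 12775 genes were called.

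Genes were named by a rule: per class, the 10 largest rises and 10 largest falls with an adjusted p under 0.05, the same direction in both libraries, at least 50 CPM (UMIs of a gene scaled to a common library total) in the higher class, a gene symbol and no part in the naming; and of each readout list up to 4 members with the largest fold among those at 10 CPM or more. This rule, the lists, the tests and most alternatives were fixed before the data were examined. Some genes that the rule names are not reported here. A fold against a class with 0 UMIs is given as a bound, against 3 UMIs over both libraries. Shares of cells with a UMI were taken after thinning each cell to 5000 UMIs; 110 cells of library 1 (11.8%) and 381 of library 2 (25.1%) are shallower and were left out, 20.0% of all cells. Intervals are exact Clopper-Pearson intervals at 95%, for counting error only, and the share that a count of 0 allows is 3 cells of the total. Gene positions are from the RefSeq annotation of GRCh38. The alternatives cover the resolution, centring, filters, doublets, another random split with parts A and B exchanged, normalisation, test, block and each replicate left out; DESeq2 1.42.0 gave the other size factors and Wald test. Where an alternative changed only the set of cells, cells in both sets kept their split and thinned UMIs. No comparison between treatments is possible with 1 group.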

Results

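The cellular make-up of day 4 blastoids was measured by single-cell RNA sequencing in 2 libraries of 1 group. Library 1 held 38665475 UMIs over 1988 barcodes and library 2 held 45208758 over 2601. After filtering, 933 and 1517 cells remained, with medians of 35008 and 25012 UMIs and of 7267 and 6305 genes per cell. With a single group, the comparisons made are between classes of cells within the libraries and between the libraries.

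Most cells carried markers shared by trophectoderm, the outer layer of the blastocyst, and amnion, and a small class carried markers of the pluripotent epiblast. The trophectoderm/amnion-like class made up 70.2% ± 11.8 of cells (SD, n = 2) and the epiblast-like class 6.15% ± 0.40 (SD, n = 2). No cluster was named endoderm-like. Library 1 had 733 of 933 cells in the trophectoderm/amnion-like class (78.6%, 95% exact interval 75.8 to 81.2) and library 2 had 938 of 1517 (61.8%, 59.3 to 64.3). The epiblast-like class held 60 cells of library 1 (6.43%, 4.94 to 8.20) and 89 of library 2 (5.87%, 4.74 to 7.17). Unnamed clusters held 23.7% ± 12.2 of cells (SD, n = 2), 140 of 933 in library 1 and 490 of 1517 in library 2 (32.3%). Each of them scored best on the trophectoderm or amnion list, with 9 to 14 of its 14 markers at 10 CPM or more. They stayed unnamed because their depth was only 0.100 to 0.285 of that of their libraries, with no such marker among their leading genes. The widest gap was cluster 2, with 12 cells in library 1 and 361 in library 2 and a median of 2527 UMIs, under 1/3 of the depth of its library. With no filter on cells the trophectoderm/amnion-like share was 45.3% and the epiblast-like share 3.13%. With no filter and another random split of the UMIs into parts A and B they were 39.8% and 3.15%, and a cluster named mesenchyme-like held 7.39% ± 1.43 of barcodes (SD, n = 2), 200 of which were trophectoderm/amnion-like with the filter.

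**Figure D1:**
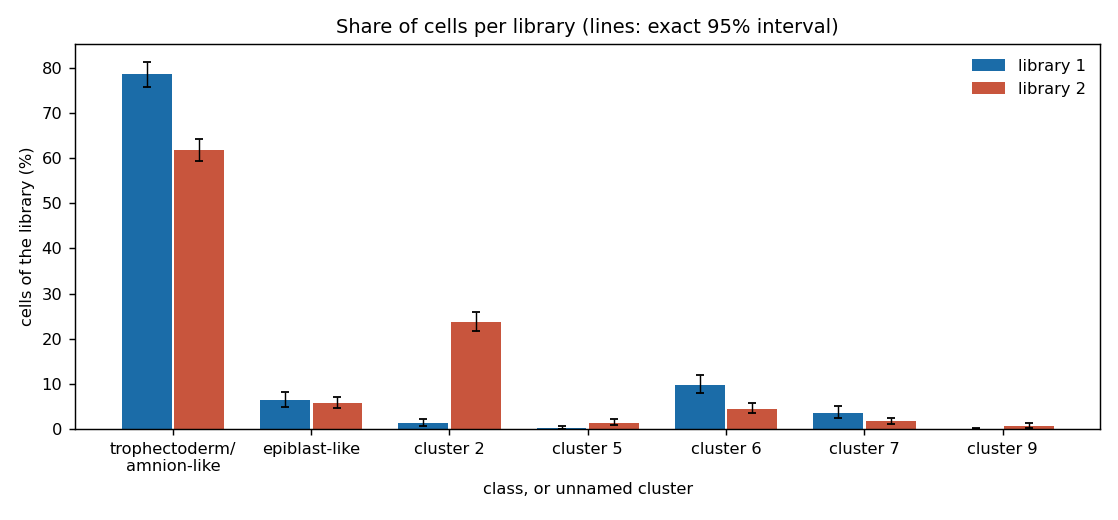
Share of the cells of each library (y axis, percent) in the named classes and in each unnamed cluster (x axis); lines are exact 95% intervals for counting error only. The epiblast-like share was 6.43% in library 1 and 5.87% in library 2, and cluster 2 lay almost wholly in library 2.

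The epiblast-like class was itself mixed, and 3 sub-clusters were found in it. In the first, of 59 cells, the pluripotency factors POU5F1 and SOX2 stood at 752 ± 101 and 147 ± 5.3 CPM (SD, n = 2). In the second, of 58 cells, POU5F1 stood at 484 ± 152 CPM beside GATA3, a trophectoderm and amnion factor, at 166 ± 25 CPM (SD, n = 2), and the marker list it matched best was that of trophectoderm or amnion. In the third, of 32 cells, TBXT and MESP1, factors of the primitive streak and early mesoderm, stood at 214 ± 71.6 and 243 ± 121 CPM (SD, n = 2), and SOX2 had 1 UMI. The list the third matched best was that of primitive streak and mesoderm, so only the first matched the pluripotent epiblast list best. This score set each sub-cluster against the mean of the 3, not of all clusters, so it shows how they differ from each other. Scored among all clusters, the 149 cells together matched the pluripotent epiblast list best. The first held 14 of the 60 epiblast-like cells of library 1 and 45 of the 89 of library 2, the second 32 and 26, and the third 14 and 18. Every comparison with the epiblast-like class is therefore one with a mixture whose make-up differed between the libraries. Within the trophectoderm/amnion-like class, 8 of the 10 mesenchyme markers tested were higher than in the epiblast-like class and 1 was lower; the list itself was not tested. The log2 fold change was 5.27 for LUM, 4.83 for DCN and 4.16 for COL3A1, which encode matrix proteins, 0.92 for COL1A1, -0.44 for COL1A2 and -0.52 for TWIST1, which did not pass.

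Levels per library were as follows. POU5F1 stood at 95.8 ± 24.2 CPM (SD, n = 2), NANOG at 3.45 ± 1.99 and SOX2 at 11.3 ± 1.76. GATA3 stood at 155 ± 12.9 CPM (SD, n = 2), GATA2 at 25.2 ± 7.57 and TFAP2A at 189 ± 0.57. Endoderm factors were low: SOX17 at 1.07 ± 0.26 CPM (SD, n = 2) and GATA4 at 2.30 ± 0.098, with GATA6 at 29.1 ± 0.35. TBXT stood at 6.64 ± 1.58 CPM (SD, n = 2). FOXA2 was analysed in library 2 alone, at 0.297 CPM, and PAX6 was not analysed here. After thinning, POU5F1 had a UMI in 72.1% ± 10.9 of epiblast-like cells and 15.8% ± 0.13 of trophectoderm/amnion-like cells (SD, n = 2); these classes had median depths of 57338 and 37331 UMIs in library 1 and 50857 and 33604 in library 2. GATA3 had one in 18.6% ± 7.24 and 44.7% ± 1.57 (SD, n = 2). Without thinning, 51.9% of all cells had a POU5F1 UMI, against 20.5% with it; in library 1 this was 91.7% of epiblast-like and 59.2% of trophectoderm/amnion-like cells, and for GATA3 65% and 87.9%, and in library 2 it was 89.9% and 58.6%, and 36.0% and 88.3%. SOX17 had a UMI in 0 of 707 trophectoderm/amnion-like cells of library 1, which allows a share of up to 0.424%, and in 0 of 913 of library 2, which allows up to 0.329%. These limits are for detection after thinning. Without it, SOX17 had a UMI in 0% of the class in library 1 and 0.213% in library 2.

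POU5F1 and GATA3 were found in the same cell in a share near or below that of independent detection. The share of free RNA was not estimated for either gene, so part of the joint detection may not come from the cell itself. Both had a UMI in 62 of 823 cells of library 1 (7.53%, 95% exact interval 5.82 to 9.55; 8.36% expected) and in 90 of 1136 of library 2 (7.92%, 6.42 to 9.65; 9.49% expected), and the expected shares lay inside both intervals, so a difference was not detectable at this depth. Over 100 other random thinnings of the same cells to 5000 UMIs the expected share exceeded the share found in 98 for library 1 and 99 for library 2, but lay above its interval in 7 and 16. With thinning to 2000 UMIs it lay just above the interval in library 2, as in 27 of 100 other such thinnings. POU5F1 and SOX17 met in 1 and 2 cells, or 0.122% and 0.176%, where independent detection would give 0.0235% and 0.0574%. GATA3 and SOX17 met in 0 cells of both libraries, which allows shares of up to 0.365% and 0.264%. For this pair independent detection would give 0.0526% and 0.115%, within those limits, so the count of 0 decides nothing.

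How the trophectoderm/amnion-like class differed from the epiblast-like class was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The largest rise among the genes named by rule was STMN2, a regulator of microtubules, with a log2 fold change of 5.58 (SE 0.32), from 1.62 ± 1.23 to 75.3 ± 1.47 CPM (SD, n = 2; edgeR adjusted p = 2.24e-66). NDNF followed at 5.37, PAPPA2, a protease that cleaves IGF-binding proteins, at 4.77, from 28.8 ± 27.0 to 751 ± 15.2 CPM (SD, n = 2), and TGFBI, a matrix protein, at 4.57. KCNMA1 and KCNQ5, potassium channel subunits, rose by 4.53 and 4.32, ITGA8, an integrin, by 4.40, COL12A1, a collagen, by 4.36, KANK4 by 4.24 and LINC01924 by 4.19. Several of these folds differed between the libraries: in library 1 alone PAPPA2 stood at 3.98, KCNQ5 at 3.59 and KANK4 at 3.33, and in library 2 alone at 6.22, 5.44 and 5.78. STMN2 and NDNF stood at 4.76 and 4.28 in library 1 alone. In library 2 they had too few epiblast-like UMIs for a fold of their own. Over both libraries they had 7 and 8 epiblast-like UMIs. Among falls, ZIC2, a zinc finger factor of the primed epiblast, had a log2 fold change of -8.45 (SE 0.29), from 87.1 ± 30.1 to 0.228 ± 0.15 CPM (SD, n = 2; edgeR adjusted p = 3.33e-181). Its level in the trophectoderm/amnion-like class rested on 8 UMIs. MIR302CHG, host of the miR-302 cluster of pluripotent cells, stood at -8.34, the WNT target SP5 at -8.13, the cell cycle gene CCND1 at -7.00 and the WNT antagonist SFRP2 at -6.73. HPAT5 stood at -8.40, ZNF804B at -7.66, ADCY2 at -7.26 and TSPEAR at -6.95. On GRCh38, ZIC2 lies on chromosome 13 from 99981784 to 99986765, STMN2 on chromosome 8 from 79611117 to 79666158 and PAPPA2 on chromosome 1 from 176463175 to 176845601.

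**Figure D2:**
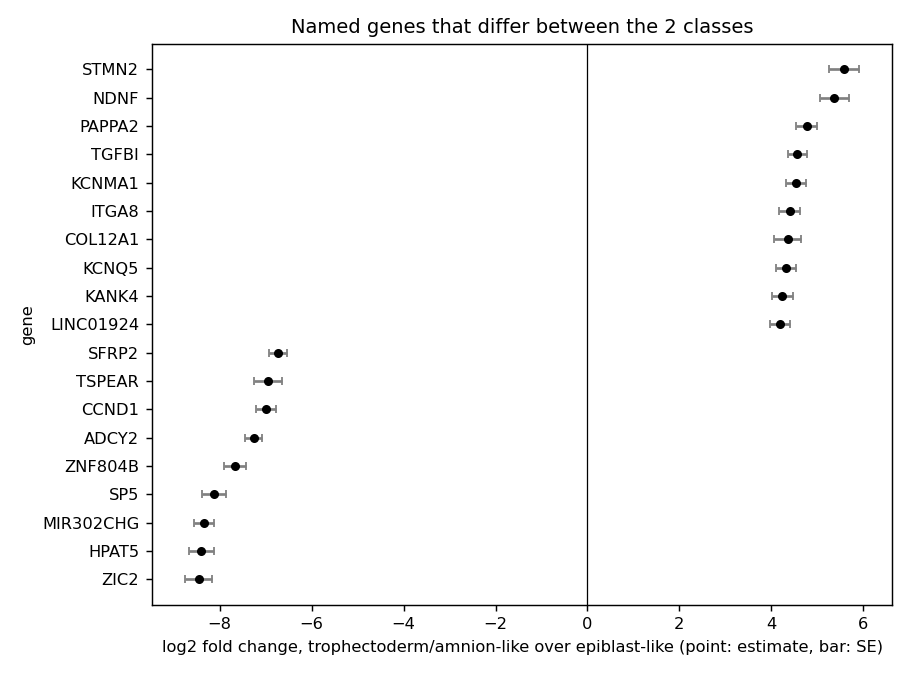
Log2 fold change of the trophectoderm/amnion-like over the epiblast-like class (x axis) for genes named by the rule (y axis). Points are edgeR estimates and bars are SEs derived from the fold and the F statistic, not counting errors. STMN2 stood at 5.58 and ZIC2 at -8.45.

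Over all genes, edgeR called 6080 of 12775 at an adjusted p under 0.05, 2464 higher and 3616 lower in the trophectoderm/amnion-like class, and 2657 of these differed at least 2-fold. That is 40.5% higher; with DESeq2 size factors the split was 3047 higher (50.7%) and 2960 lower, and the median log2 fold change of all genes moved from -0.10 to 0.021, so small differences depend on the scaling. With another random split and parts A and B exchanged 50.6% of calls were higher, with doublets kept 50.1%, and with doublets kept and another split 36.4%. DESeq2's Wald test called 3503. Without the sub-cluster highest in GATA3, 5368 of 10022 genes were called.

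Of the lists, camera called 12 in this class, and with an estimated correlation 0 passed. The fit left few residual degrees of freedom for that estimate, and most calls shared an adjusted p of 0.498 under it. It therefore hardly separates the lists and decides little about any 1 call. Genes of amnion and of trophectoderm both rose. Of the amnion list, 13 of 14 members tested rose and 1 fell, the same adjusted over the list alone: the integrin ITGB6 by 4.04 (log2; 4.68 in library 2 alone), the GABA receptor subunit GABRP by 3.89, to 463 ± 2.79 CPM (SD, n = 2), and IGFBP5 by 3.34 (2.56 in library 1 alone and 4.55 in library 2), while POSTN stood at -3.46 (camera adjusted p = 1.81e-08, adjusted p = 0.498 with an estimated correlation). Of the trophectoderm list, 7 of 10 rose and 2 fell, and also adjusted over the list alone: VGLL1 by 2.98, NR2F2 by 2.85 and LRP2 by 2.57, while CDX2, an early trophectoderm factor, stood at -4.66, from 37.3 ± 1.30 to 1.5 ± 0.0055 CPM (SD, n = 2) (camera adjusted p = 3.82e-03, adjusted p = 0.524 with an estimated correlation). In the epiblast-like class CDX2 was highest in the sub-cluster with TBXT, at 120 ± 23.7 CPM (SD, n = 2). Of desmosome and keratin genes 6 of 10 rose and 1 fell, the same adjusted over the list alone, with PKP2 at 1.94 and PERP at 0.99 (camera adjusted p = 5.80e-03, adjusted p = 0.498 with an estimated correlation). Of YAP and TEAD targets 7 of 12 rose and 2 fell, the same adjusted over the list alone, with ANKRD1 at 3.14 and TGFB2 at 3.02 but CCN2 at -1.24 (camera adjusted p = 0.0287, adjusted p = 0.537 with an estimated correlation; 0.0512 with cells of 5000 UMIs or more alone).

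Genes of primed pluripotency, WNT signalling, cholesterol synthesis and the cell cycle fell. Of the primed list 13 of 14 fell and 1 rose, the same adjusted over the list alone, with SFRP2 at -6.73 (camera adjusted p = 1.92e-07, adjusted p = 0.498 with an estimated correlation). Of WNT targets 9 of 10 fell, the same adjusted over the list alone, with DKK1 at -5.85, WNT3 at -5.52 and NKD1 at -5.11 (camera adjusted p = 4.90e-06, adjusted p = 0.498 with an estimated correlation). All 9 primitive streak and mesoderm markers tested fell too, though that list itself was not tested. Within the epiblast-like class the WNT targets LEF1 and NKD1 were highest in the sub-cluster with TBXT, at 274 ± 25.5 and 124 ± 33.0 CPM, against 112 ± 65.3 and 33.8 ± 1.92 in the sub-cluster highest in SOX2 (SD, n = 2). Of cholesterol synthesis genes 15 of 17 fell, the same adjusted over the list alone, with the squalene epoxidase gene SQLE at -2.74 (camera adjusted p = 2.18e-07, adjusted p = 0.498 with an estimated correlation). Of S phase genes 32 of 42 fell, 34 adjusted over the list alone, with MCM2 at -1.25 and RRM2 at -1.16 (camera adjusted p = 2.30e-06, adjusted p = 0.498 with an estimated correlation). Of G2 and M phase genes 33 of 52 fell, the same adjusted over the list alone, with CENPE at -1.59 and BUB1 at -1.15 (camera adjusted p = 6.75e-05, adjusted p = 0.498 with an estimated correlation).

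Genes of energy metabolism and p53 targets also fell. Of oxidative phosphorylation genes 10 of 19 fell, the same adjusted over the list alone, with ATP5MC1 at -0.95 (camera adjusted p = 0.0130, adjusted p = 0.738 with an estimated correlation; adjusted p = 0.0734 with fry, which tests whether the genes of a list move one way and does not compare them with other genes). Of glycolysis genes 11 of 17 fell and 3 rose, the same adjusted over the list alone, with ENO1 at -1.30 and PFKP at 1.70 (camera adjusted p = 0.0288, adjusted p = 0.537 with an estimated correlation). Of p53 targets 8 of 13 fell, the same adjusted over the list alone, with TNFRSF10B at -1.47, not called by DESeq2's Wald test (camera adjusted p = 0.0499, adjusted p = 0.577 with an estimated correlation). Without the sub-cluster highest in GATA3 these 3 calls ended, at camera adjusted p = 0.0894, 0.0894 and 0.274, and the p53 call also ended with no replicate block, at 0.0524.

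The other lists did not pass camera; beyond the BMP and definitive endoderm lists, their adjusted p ranged from 0.127 for matrix genes to 0.918 for hypoblast genes. Of BMP and SMAD1/5 targets 8 of 11 fell and 2 rose, with MSX1 at -3.77 and ID3 at -2.19 (adjusted p = 0.0527). This list passed camera with DESeq2 size factors, from all UMIs and with cells of 5000 UMIs or more alone, at adjusted p = 0.0357, 0.0411 and 0.0492. Its fry adjusted p, which does not set it against other genes, was 0.0235. All 3 definitive endoderm genes tested fell, with CYP26A1 at -5.74 and CER1 at -5.38 (adjusted p = 0.0586; 0.0414 with DESeq2 size factors; fry adjusted p = 0.0194). Their epiblast-like levels lay mostly in library 2, CYP26A1 at 14.5 CPM in library 1 and 38.6 in library 2, and CER1 at 0.997 and 25.5, so the fold of CER1 rests on library 2. Of hypoblast genes 4 rose and 4 fell, with NID2 at 2.76 and RSPO3 at -5.10; the list median was -0.19 while camera's direction was up. Of matrix genes 9 of 13 rose and 4 fell, VCAN standing at -3.17. Of tight junction genes 5 of 13 rose and 1 fell, with PARD6B at 1.44; the 1 that fell, EZR, stood at -0.65, was not called with another random split and parts A and B exchanged, and stood at 0.72 without the sub-cluster highest in GATA3, where camera called the list up (adjusted p = 3.21e-04). Its median log2 fold change was -0.04 and its mean 0.25. Of imprinted genes 6 of 12 rose and 4 fell, with H19 at 3.92 and PLAGL1 at -2.70 (-1.49 in library 1 alone and -3.47 in library 2). Of ion and water transport genes 3 of 6 rose and 3 fell, with SLC12A2 at 1.79 and SCNN1A at -1.90; the median was -0.18 and the mean 0.06. Of hypoxia genes 5 of 14 rose and 4 fell, with ADM at -4.11; the median was 0.06 and the mean -0.06. Of immediate early genes 4 of 15 rose and 3 fell, with JUN at 1.66. Of unfolded protein response genes 2 of 10 rose and 5 fell, and of class I antigen presentation genes 3 of 6 fell. All these counts were the same adjusted over the list alone. Of extravillous trophoblast genes 2 of 4 fell, with 1 more rising adjusted over the list alone, and of syncytiotrophoblast genes 1 of 3 fell, the same adjusted over the list alone. Of naive pluripotency genes 0 of 2 passed, also adjusted over the list alone, with KLF5 at -0.35, and no eight-cell gene was abundant enough to be tested.

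**Figure D3:**
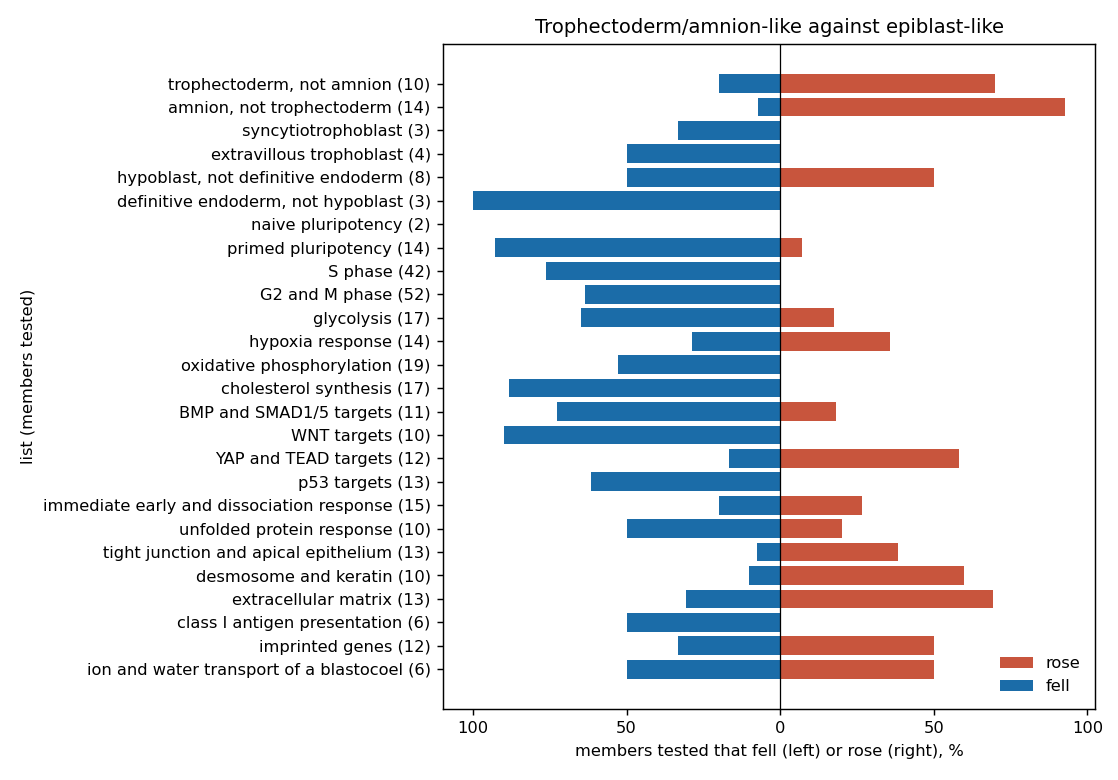
Share of the tested members of each list (x axis, percent) that fell (left) or rose (right) in the trophectoderm/amnion-like against the epiblast-like class in edgeR; the number tested stands in brackets beside the list (y axis). The amnion list had 13 of 14 members up and the primed pluripotency list 13 of 14 down.

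Cluster 6, with 92 and 69 cells and a median of 3680 UMIs, had a median of 0.135% mitochondrial UMIs and 26.7% from ribosomal protein genes. Compared with the epiblast-like class, SLN, a regulator of the calcium pump, stood at 64.6 ± 10.7 against 0.249 ± 0.35 CPM (SD, n = 2), the latter from 1 UMI. STMN2 stood at a log2 fold change of 6.81 (SE 0.44), the neuropeptide gene NPY at 5.10, the cell cycle inhibitor CDKN1C at 4.75, from 25.6 ± 5.43 to 544 ± 6.23 CPM (SD, n = 2), the growth factor gene PTN at 4.41 and VIM at 4.22. ADCY2, an adenylyl cyclase gene, had 0 UMIs in the cluster and was at least 44.2-fold lower, and NKAIN2 at least 22.7-fold. In the trophectoderm/amnion-like class ADCY2 also fell, at -7.26, and STMN2 also rose, at 5.58. Nuclear RNAs were low in cluster 6 as well, as given further below. How far that shapes the folds and list calls of this cluster was not tested. edgeR called 1915 genes higher (43.6%) and 2476 lower; with no normalization factors these were 1234 (26.7%) and 3394, and the median log2 fold change of all genes moved from -0.23 to -0.57. With DESeq2's Wald test the majority turned, to 2081 higher (57.0%) and 1567 lower, as it did without the sub-cluster highest in GATA3, to 2225 (50.9%) and 2146. In library 1 alone STMN2 stood at 5.90, NPY at 4.44, PKP3 at 2.58 and H19 at 3.39, and in library 2 alone NLGN4X at -4.45. These were scaled by UMI totals without TMM factors, which lowers the folds of cluster 6 over the epiblast-like class. Of oxidative phosphorylation genes 16 of 19 rose, 17 adjusted over the list alone, with NDUFA1 at 1.31 (camera adjusted p = 9.66e-08, adjusted p = 0.498 with an estimated correlation). Of amnion genes 10 of 14 rose, the same adjusted over the list alone, with GABRP at 3.69 (camera adjusted p = 3.12e-05, adjusted p = 0.498 with an estimated correlation). Of imprinted genes 7 of 12 rose and 1 fell, 7 and 2 adjusted over the list alone, with H19 at 4.17 (camera adjusted p = 4.95e-03, adjusted p = 0.498 with an estimated correlation). Of WNT targets 6 of 10 fell, the same adjusted over the list alone, with LEF1 at -3.27 (camera adjusted p = 5.23e-04, adjusted p = 0.498 with an estimated correlation). Of desmosome and keratin genes 6 of 10 rose, the same adjusted over the list alone, with PKP3 at 3.23 (camera adjusted p = 0.0200, adjusted p = 0.498 with an estimated correlation; 0.0692 with cells of 5000 UMIs or more alone). Of immediate early genes 5 of 15 rose and 1 fell, the same adjusted over the list alone, with JUN at 1.47 (camera adjusted p = 0.0313, adjusted p = 0.577 with an estimated correlation; 0.146 without the sub-cluster highest in GATA3, 0.0692 with cells of 5000 UMIs or more alone; fry adjusted p = 0.0848). Of primed pluripotency genes 8 of 14 fell and 2 rose, 9 and 2 adjusted over the list alone, with NLGN4X at -3.76 (camera adjusted p = 0.0485, adjusted p = 0.670 with an estimated correlation; 0.0668 with no replicate block, 0.0615 from all UMIs, 0.0754 with cells of 5000 UMIs or more alone; fry adjusted p = 0.0734).

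Cluster 7, with 34 and 27 cells and a median of 4155 UMIs, had a median of 9.17% of UMIs from ribosomal protein genes, against 15.2% in the epiblast-like class, and most of its leading genes had no symbol or were non-coding. It was led by PLCG2, which encodes a phospholipase C, at 7278 ± 2309 against 36.0 ± 17.5 CPM (SD, n = 2), a log2 fold change of 7.46 (SE 0.28). TEX14 stood at 203 ± 10.9 against 1.31 ± 0.26 CPM (SD, n = 2). GAL, the galanin gene, had 0 UMIs in the cluster and was at least 29.1-fold lower, and the phosphatase gene PTPRZ1 at least 12.7-fold. How far the low depth and low ribosomal share shape the folds and list calls of cluster 7 was not tested. NDUFB2 and PGAM1, named below, had 7 and 5 UMIs in the cluster. Apart from immediate early genes, each list given below was also called the same way in the trophectoderm/amnion-like class. edgeR called 1268 genes higher (41.1%) and 1818 lower; with no normalization factors these were 1519 (55.0%) and 1245, and the median log2 fold change of all genes moved from -0.25 to 0.0047. DESeq2's Wald test gave 1736 higher (65.2%) and 926 lower. In library 1 alone PGAM1 stood at -2.15 and ATF3 at 3.69, and in library 2 alone NDUFB2 at -2.15 and VTCN1 at 4.07. These were scaled by UMI totals without TMM factors, which raises the folds of cluster 7 over the epiblast-like class. Of oxidative phosphorylation genes 18 of 19 fell, 19 adjusted over the list alone, with NDUFB2 at -2.84 (camera adjusted p = 4.51e-08, adjusted p = 0.498 with an estimated correlation). Of S phase genes 27 of 42 fell, 30 adjusted over the list alone (camera adjusted p = 1.64e-09, adjusted p = 0.498 with an estimated correlation), and of G2 and M phase genes 28 of 52 fell, 38 adjusted over the list alone (camera adjusted p = 9.98e-09, adjusted p = 0.498 with an estimated correlation). Of immediate early genes 6 of 15 rose and 1 fell, the same adjusted over the list alone, with JUN at 2.92 and ATF3 at 2.88 (camera adjusted p = 4.95e-03, adjusted p = 0.524 with an estimated correlation). Of amnion genes 10 of 14 rose, 11 adjusted over the list alone, with VTCN1 at 3.15 (camera adjusted p = 2.70e-04, adjusted p = 0.498 with an estimated correlation). Of primed pluripotency genes 10 of 14 fell and 1 rose, 11 and 1 adjusted over the list alone (camera adjusted p = 3.90e-05, adjusted p = 0.498 with an estimated correlation). Of WNT targets 4 of 10 fell and 1 rose, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.498 with an estimated correlation). Of glycolysis genes 10 of 17 fell and 1 rose, the same adjusted over the list alone, with PGAM1 at -3.28 (camera adjusted p = 0.0194, adjusted p = 0.524 with an estimated correlation). Of cholesterol synthesis genes 7 of 17 fell, the same adjusted over the list alone (camera adjusted p = 0.0313, adjusted p = 0.738 with an estimated correlation; 0.0531 without the sub-cluster highest in GATA3; fry adjusted p = 0.132).

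The libraries were alike gene by gene. Across 25556 genes, which are not independent replicates, log2(CPM + 1) had a Pearson correlation of 0.998 and a Spearman correlation of 0.991; within the epiblast-like class these were lower, at 0.986 and 0.964. Of 4149 genes at 50 CPM or more in either library, 2 differed more than 2-fold, of which CLDN10, a claudin gene chosen after its values were seen, stood at 38.5 and 84.3 CPM; the other has no symbol. POU5F1 stood at 78.7 CPM in library 1 and 113 in library 2. A chi-square of the summed counts over its degrees of freedom was 7.06, above the sampling noise of UMIs. UMIs come in cells and the libraries differed in the share of cluster 2, so this value does not tell separate cultures from parts of 1 culture. They were counted as 2 replicates because the labels list them as separate samples.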

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

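The low depth test, the sub-cluster's free RNA test, the spread in cluster 2 without its most deviating cells and the genes named in clusters 2 and 5 were chosen after the result was seen, as were the narrower gene sets, of 8-fold or of 50 CPM and more, whose values stand beside those of the free RNA and doublet tests. No biological explanation was tested, since the design has 1 group.

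Cluster 5 was not used in the comparisons, because library 1 had 2 of its cells and library 2 had 22. It stands here because 3 genes of the syncytiotrophoblast, the hormone-producing layer of the placenta, had more UMIs than a count of 0 allows, a low bar with no control samples, so their levels in all other cells stand beside them. CGA, a subunit of chorionic gonadotropin, had 450 UMIs there, at 905 CPM against 6.66 in other cells. CYP19A1, the aromatase gene, had 644, at 1295 CPM against 8.49, and ERVW-1, which encodes the fusion protein syncytin, 127, at 255 CPM against 0.137. The 2 cells of library 1 carried 378, 419 and 119 of these UMIs, so most of them came from 2 cells. The 22 cells of library 2 carried 72, 225 and 8. These counts are not scaled to depth, so they do not show how the level differed between the libraries.

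Cluster 6 had a median of 0.135% mitochondrial UMIs. Other cells of the same depth had a median of 4.01%, which argues against low depth alone. Free RNA of one mixture would give each cell the same split between genes of the epiblast-like and trophectoderm/amnion-like classes, but this split varied between cells far beyond a binomial draw, with a chi-square over degrees of freedom of at least 163 in both libraries, and at least 50.9 over genes differing 8-fold or more. Nuclear RNAs such as MALAT1 stood at a median of 0.0368 and 0.105 of their level in the trophectoderm/amnion-like class, under the bound of 0.5 set beforehand. Cytoplasm that lost its nucleus and mitochondria stays open as a candidate explanation.

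Of the 3984 genes at 50 CPM or more in trophectoderm/amnion-like cells of library 2, where cluster 2 almost wholly lay, 99.7% stood within a factor of 2 in the cluster, consistent with most of it being shallow cells of that class. Lower genes were not part of that test: CER1 had 50 UMIs in 4 of its 361 cells of library 2, SOX17 12 in 4, and POU5F1, NANOG, TDGF1 and EOMES stood at 62.6, 3.29, 6.59 and 5.93 CPM against 35.6, 0.276, 0.332 and 0.304 in the class, so some cells of other kinds are not excluded. Free RNA of one mixture as the only source is argued against by a chi-square over degrees of freedom of 38.3 (15.9 without the 10% of cells that deviate most), and 10.6 (2.25) over genes differing 8-fold or more. As a part of the UMIs it stays open, since the share from epiblast-high genes, 44.4%, lay nearer to the 45.7% of all cells of library 2 than to the 41.2% of the class. A larger number of shallow barcodes in library 2 is not enough, since the cluster's share of cells under 5000 UMIs was 10.2 times that in library 1; why library 1 has few such cells was not tested.

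The epiblast-like sub-cluster of 58 cells with GATA3 and POU5F1 had the highest median depth of the 3, at 66667 UMIs, so doublets are one possible explanation. Doublets would hold the genes of the trophectoderm/amnion-like class in one ratio. Over all 6562 genes of the test as first set out, 58.3% lay within a factor of 2 of the median ratio, but that median was 0 since most of these genes had no UMI, so the test is void; over the 189 genes at 50 CPM or more, a floor added later, 66.7% did, between the bounds of 50 and 80. Free RNA would leave no gene at the full level of the class; 393 genes stood at 0.8 or more of it in both libraries, with a median of 3 UMIs in the sub-cluster, and 6 did at 50 CPM or more, among them GATA3, TFAP2A and ISL1. Over those 189 genes the ratio ran from 0.0111 to 1.95, a range looked at later. A single diluted copy of the class would not give that, which argues against free RNA as the only source. Doublets with cells of the mean profile of the class would not give that range either. Doublets with cells of 1 cluster of the class, whose clusters differ in GATA3, were not tested. The doublet caller assumed 0.75% and 1.22% of barcodes, while this sub-cluster held 32 of 933 and 26 of 1517 cells. Doublets at those rates would be too few to make up all of it. The rates were assumed from the number of barcodes left after filtering and were not measured, so this does not exclude doublets. As parts of it, doublets, free RNA and cells between both classes cannot be told apart here. Genes near the floor decide nothing, and the rest fell between the bounds.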

How the results depend on the processing

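The settings without the sub-cluster highest in GATA3, with cells of 5000 UMIs or more alone, with the named classes alone, with no normalization factors, with a filter or doublet setting and another split, with other random thinnings and cluster by cluster, and the shares with another split and parts exchanged, were chosen after seeing the data. The epiblast-like share of 6.15% was 4.30% at resolution 0.25, 4.80% with genes centred within library, 5.37% from all UMIs, 3.13% with no filter on cells, and 8.12% of the named classes alone. With no filter the trophectoderm/amnion-like and unnamed shares were 45.3% and 51.5%, and with at least 2000 genes and at most 10% mitochondrial UMIs 86.5% and 7.20%. With another random split of the UMIs beside the filter, the 3 shares were 3.15%, 39.8% and 49.7% with no filter, a cluster named mesenchyme-like holding the other 7.39%, and 6.86%, 85.3% and 7.79% with the stricter one. The filters change which barcodes are counted. Without one 1643 of 1671 trophectoderm/amnion-like cells kept their name, and 1452 with another split, where 200 became mesenchyme-like. Of 149 epiblast-like cells, 41 became trophectoderm/amnion-like at resolution 0.25, 29 with genes centred, 21 from all UMIs, 20 with another split and parts A and B exchanged, 14 with no filter and 10 with doublets kept, as did 30 of the 134 left by the stricter filter. The cause of these and the other shifts was not tested. From 1 library each, the shares ranged from 5.87% to 6.43%, 61.8% to 78.6% and 15% to 32.3%. The count of genes called for the trophectoderm/amnion-like class was 3503 with DESeq2's Wald test (1543 higher, 1960 lower), and with no filter on low counts 3725 were higher and 2941 lower; in its other settings it stayed within 1.5 times. For cluster 6, 1234 genes were higher with no normalization factors and 1567 lower with the Wald test (2081 higher). For cluster 7, 2043 were higher from all UMIs and 926 lower with the Wald test. The cause was not tested. With no replicate block 6448, 4247 and 2815 genes were called. With an estimated correlation, which rests on few residual degrees of freedom, 0 lists were called in each of the 3 comparisons. Of the list calls under other settings, leaving out the sub-cluster highest in GATA3 ended 5 and added 8, cells of 5000 UMIs or more alone ended 4 and added 2, no replicate block ended 2, all UMIs ended 1 and added 3, and DESeq2 size factors added 2. Fry, which does not compare a list with other genes, did not pass 4 of the lists camera called and passed 6 others. Of the calls of named genes, 36 ended with the Wald test, 12 with no normalization factors, 11 with no filter on low counts, 9 with cells of 5000 UMIs or more alone, 6 with no replicate block, 5 without that sub-cluster, 4 with another split and parts A and B exchanged, 3 each from all UMIs and with DESeq2 size factors, 3 with doublets kept (2 with another split as well) and 1 with the named classes alone. POU5F1 and GATA3 met in 2.01% of cells at 2000 UMIs, with the expected share of 1 library above its interval, in 7.70% with doublets kept and in 5.96% to 9.13% over 100 other random thinnings to 5000, and GATA3 and SOX17 in 0.0547% at 2000 UMIs. Without the sub-cluster highest in GATA3, EZR turned to 0.72 and KLF5, not called before, to 1.85. In cluster 6, TGFB2 stood at -0.12 in library 1 alone and at 2.37 in library 2 alone, scaled by UMI totals. Its call used TMM factors, which raise the folds of cluster 6, so the sign in library 1 does not show a reversal. Of the called folds named by rule, where a library had over 3 UMIs in both classes, 12 of 99 for the trophectoderm/amnion-like class, 23 of 53 for cluster 6 and 21 of 34 for cluster 7 moved by over 1.5 times in 1 library alone. The folds from 1 library were scaled by UMI totals, while those they were set against used TMM factors. In library 1 these factors were 0.748 for cluster 6 and 1.04 for the epiblast-like class. Part of the moves is therefore scaling, and the counts for clusters 6 and 7 do not measure disagreement of the libraries alone. Folds from 1 library have no test. Clusters 6 and 7 have no counterpart with fixed numbers when cells are clustered again, so they have no value with another split and parts A and B exchanged or doublets kept. Clusters 6 and 7 rest on 469901 and 168502 part B UMIs, which limits what can be seen of low genes.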

Other observations

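All values in this part were chosen after the data were seen, and none was tested. Within the trophectoderm/amnion-like class, cluster 4, of 33 and 68 cells, stood apart from the rest in several genes. GATA3 stood at 341 CPM there, against 128, 155 and 107 in clusters 0, 1 and 3, and GATA2 at 91.5 against 10.9, 13.8 and 8.3, while TFAP2A was about as high there, at 198 against 210, 199.8 and 197. The nuclear receptor gene PPARG stood at 227 CPM against 72.0, 115 and 66.1, and the imprinted gene PEG10 at 609 against 154, 107 and 126. VTCN1, an amnion gene of the readout lists, was lower there, at 132 against 210, 363 and 189 CPM. The proliferation gene MKI67 stood at 192 CPM in cluster 3, against 76.6, 29.9 and 106 in clusters 0, 1 and 4, and TOP2A at 538 against 143, 56.7 and 215. CCNB2, a cyclin of mitosis, was about as high in cluster 0, at 98.0 CPM, as in cluster 3, at 88.9.

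The epiblast-like sub-cluster with TBXT also had MSGN1 at 185 ± 70.0 CPM, TBX6 at 95.1 ± 28.9, the WNT agonist RSPO3 at 326 ± 60.5 and GATA6 at 137 ± 5.4 (SD, n = 2), where the sub-cluster highest in SOX2 had 2 UMIs of RSPO3 and GATA6 at 16 CPM. SOX2 and NODAL stood at 147 ± 5.3 and 92.8 ± 49.6 CPM in the latter (SD, n = 2). The 11 cells of cluster 9, all in library 2, were led by SPP1, the osteopontin gene, at 8047 CPM.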
